A study of Mus musculus with 8 samples.

How the data were processed

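Total RNA from the cerebral cortex of mice at postnatal day 0 was extracted with Trizol and cleaned on RNeasy columns with DNase I, and biotinylated cRNA was made for Illumina bead arrays, per the labels' protocols. The labels give 2 genotypes, wild type and ERRγ-null, with 2 biological samples each and a technical replicate array for each sample, so that there were 8 arrays from 4 samples. Whether a biological sample was 1 animal or a pool, and the sex and strain of the mice, is not given in the sources used here. The p-values therefore measure only the spread between these samples, which may in part be technical.

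The deposited values were 1 mean bead intensity per probe and array, on a linear scale, neither background-subtracted nor normalized between arrays as far as the values show. A detection p-value per probe and array, which sets the probe against background, was deposited beside each intensity, per the file headers. GenomeStudio is named in the submitters' processing notes, and its version and settings are not given in the sources used here. A second deposited table held intensities of the same arrays which the authors had brought to 1 common distribution. It was linear, its column medians ran from 142.5 to 142.7, and its rank correlation with the unnormalized intensity was 1 on each array. It was used as an alternative. The name of the method that made it, and whether it was made before or after any background step, stays unknown.

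Analysis started from the unnormalized intensities. In R 4.3.3 with limma 3.58.1, neqc estimated the background through the detection p-values (normexp), added an offset of 16, applied quantile normalization and took log2. Probes were kept when the detection p was under 0.05 on at least 4 of the 8 arrays, which left 11568 of 25697 probes. Of all probes, 23846 had 1 gene symbol in the platform annotation, 0 had several and 1851 had none. The Entrez identifiers of 23830 probes matched a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. That table was used for names and for the order of neighbouring genes only, and no coordinates are given because the files name no genome build. A gene was represented by its brightest kept probe, which mattered for 2003 genes with more than 1 kept probe, and 8098 genes were tested. The 782 kept probes without a symbol were fitted separately.

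The 2 arrays of a sample were averaged after normalization, so that n is 2 per genotype. Genotypes were compared with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The prior had 14.0 degrees of freedom and each gene 2 residual ones. Differences are ERRγ-null minus wild type on the normalized log2 scale. A gene not above background on any array of 1 genotype was given as a lower limit of its fold. For that limit, each dim array took the higher of the probe's own value and the lowest signal among probes above background. The limit concerns the measured means and does not include sampling error. Differences between arrays were described by the SD of log2 differences over the tested genes.

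Gene lists, 37 in number, covered oxidative and other metabolism, neuronal function, cell types of cortex and of adjoining tissue, stress responses and neighbours of Esrrg. They were fixed, like the tests, before the data were examined. Lists with at least 3 tested members were compared with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The last tests whether a list's genes move, on balance, one way, and does not compare the list with other genes. Camera with an estimated correlation refers its statistic to the residual degrees of freedom, 2 here. Its p can therefore be larger even where the estimated correlation is negative, and it has little power here. Members were also adjusted over their list alone, with no adjustment across lists. Genes were named by a rule also fixed beforehand. It took the ERR family, then up to 12 genes per direction with non-overlapping samples. Those past the threshold came first, then those with the largest difference at an unadjusted p under 0.01. It added up to 2 or 3 members per list with the smallest p, of which the text gives the ones with the larger differences.

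The fit was tested on simulated data with 200 changed genes per run, in 20 runs over 8098 genes, where 4.96% of calls were false. The simulation drew variances from the limma fit itself and added independent normal noise. It checks that the steps run correctly under that model, and does not test correlated genes or unusually variable ones. Alternatives covered background correction, normalization, the deposited normalized table, the filter, the use of technical arrays, the variance prior, the replicate number as a block, each sample left out, the probe per gene and the threshold. A run without the first array of wild-type sample 1, the dimmest, was added after seeing the data, as were eBayes with a brightness trend alone and with robust estimation alone. Figures were drawn with matplotlib 3.10.9.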

Results

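Gene expression was measured in the cerebral cortex of newborn mice (postnatal day 0) that were either wild type or null for estrogen-related receptor gamma (ERRγ). ERRγ is an orphan nuclear receptor encoded by Esrrg and is known as an activator of genes for mitochondrial oxidative metabolism. The comparison asked which transcripts differ when the receptor is missing, in cortex at an age when, according to the submitters, it holds mostly cells of the neuronal lineage. Each genotype was represented by 2 biological samples, and each sample was hybridised to 2 Illumina bead arrays, a first array and a b array, which gave 8 arrays in all. Mean probe intensity before normalization ran from 390 on the first array of wild-type sample 1 to 639 on the b array of ERRγ-null sample 1. The 4 wild-type arrays had mean intensities of 390, 486, 504 and 565, and the 4 ERRγ-null arrays 547, 639, 567 and 561. Between 11022 and 12013 of the 25697 probes were above background on an array. The small number of samples limits the precision of every value given here.

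Cortex samples of both genotypes were close to each other. The standard deviation (SD) of the log2 differences between 2 arrays of 1 sample had a median of 0.283 over the 4 such pairs. It was 0.321 between arrays of different samples of 1 genotype (8 pairs) and 0.330 between arrays of different genotypes (16 pairs). The arrays of wild-type sample 1 were the technical pair farthest apart, with an SD of 0.345.

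The targeted gene was read by 1 probe, which was not above background on any of the 8 arrays (detection p from 0.357 to 0.761). Its normalized log2 signal was 4.92 ± 0.01 (SD, n = 2) in wild-type cortex and 4.94 ± 0.04 (SD, n = 2) in ERRγ-null cortex. The difference was 0.02 with a standard error (SE) of 0.15. The Esrrg probe therefore does not check the genotype labels, and its position relative to the deleted part of the gene is not given in the sources used here. Of the related receptors, Esrra was well above background on all arrays, at 8.53 ± 0.11 in wild-type and 8.57 ± 0.18 in ERRγ-null cortex (SD, n = 2 each). The difference for Esrra was 0.04, with a 95% confidence interval from -0.31 to 0.38. Esrrb was not above background on any array.

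Of 8098 genes tested, 1 differed between the genotypes. Xlr4a, an X-linked member of the Xlr multigene family, fell by 2.61 on the log2 scale in ERRγ-null cortex (SE 0.36, limma adjusted p = 0.0134). Its log2 signal was 9.01 ± 0.93 in wild-type cortex and 6.39 ± 0.89 in ERRγ-null cortex (SD, n = 2 each). The SE of 0.36 is smaller than these SDs alone would give. It comes from a variance that limma drew towards that of the other genes, with 14.0 prior and 2 residual degrees of freedom. Robust variance estimation, which draws unusually variable genes less, did not give the call. The wild-type samples lay at 8.35 and 9.66 and the ERRγ-null samples at 7.02 and 5.76, so that both null samples were below both wild-type samples. The transcript was above background on the 4 wild-type arrays and on 2 of the 4 ERRγ-null arrays, both of ERRγ-null sample 1, so that the value of ERRγ-null sample 2 lies at background. Xlr genes are close in sequence, and how far the probe separates Xlr4a from its relatives is not given in the sources used here. The limma adjusted p for Xlr4a was 0.180 without ERRγ-null sample 1 and 0.580 without ERRγ-null sample 2. It was also above the threshold with the first arrays alone (0.129), the b arrays alone (0.128), no filter on dim probes (0.713), robust variance estimation (0.581, and 0.734 together with a brightness trend) and the mean of all probes of a gene (0.569).

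No gene was higher in ERRγ-null cortex past the threshold (0 genes by limma, with 292 at an unadjusted p under 0.05). In all, 585 genes had an unadjusted limma p under 0.05, of which 293 were lower, where a uniform distribution of p gives 404.9. The log2 differences of all genes had an SD of 0.197 around a median of 0.00. Both samples of 1 genotype lay above both of the other for 35.1% of genes, where chance gives 33.3%. In simulated data for this comparison, with 8098 genes and the same number of samples, 16.2% of genes changed by 0.5 on the log2 scale were recovered, against 97.0% of those changed by 1. These shares hold for 200 changed genes per run, with log2 sizes of 0.5, 1 and 2. The adjustment is stricter where fewer genes change, so they do not exclude missed changes of 1 here. Scaling the arrays by their medians, in place of quantile normalization, shifted the median of all genes by 0.17 and gave 20 genes, 19 of them higher. The share of higher genes among those at an unadjusted p under 0.05 was then 93.8%, against 49.9% with quantile normalization. The count was 22 without wild-type sample 1, 17 without wild-type sample 2, and 0 without either ERRγ-null sample.

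**Figure D1:**
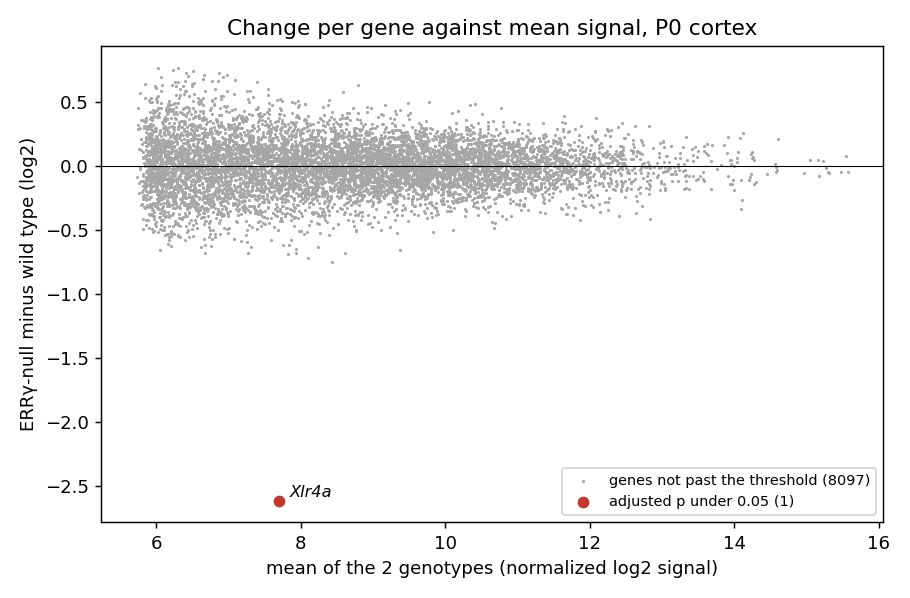
Each point is 1 of the 8098 genes tested, with the mean normalized log2 signal of the 2 genotypes on the horizontal axis and the log2 difference, ERRγ-null minus wild type, on the vertical axis. Xlr4a (red, -2.61) is the only gene past the threshold, and the scatter of the others is wider at low signal.

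The 12 genes named for the highest values in ERRγ-null relative to wild-type cortex did not pass the test. Ppargc1b, which encodes the coactivator PGC-1β, a known partner of estrogen-related receptors, had a log2 signal of 6.13 ± 0.15 in wild-type and 6.87 ± 0.18 in ERRγ-null cortex (SD, n = 2 each). The difference was 0.74 (SE 0.16, limma adjusted p = 0.377). Jund, an AP-1 transcription factor gene, differed by 0.72, and Fhl2, which encodes a LIM-domain cofactor, by 0.71. Kcnh1, a voltage-gated potassium channel gene that lies near Esrrg on chromosome 1, differed by 0.71. Dis3, the gene for a ribonuclease of the RNA exosome, differed by 0.75. Values for the other genes of this group were 0.77 for 1700029J07Rik, 0.72 for BC051142, 0.71 for 2610044O15Rik8, 0.69 for the zinc finger gene Zfp956, 0.69 for the prostaglandin transporter gene Slco2a1 and 0.68 for the lysosomal gene Ctsa. The 2 other Ctsa probes had a median difference of 0.08. Brap was not above background on any wild-type array. Its measured mean was at least 1.35-fold higher in the null samples (limma adjusted p = 0.377). That lower limit does not include sampling error. These 12 genes were dim, with a median wild-type log2 signal of 6.11 against 8.53 for all genes tested, and only Ppargc1b and Zfp956 were above background on all 4 wild-type arrays. Fhl2 was above background on 2 of them and 1700029J07Rik, Dis3 and Slco2a1 on 1. Adjusted p for these 12 genes ran from 0.377 to 0.480. With median scaling, which moved the median of all genes up, 11 of the 12 passed, and with the replicate number as a block 9 did. That block fit had infinite prior degrees of freedom. Some genes also passed without 1 of the wild-type samples. Each of the 12 passed in only 1 to 3 of 19 refitted alternatives and failed in the others.

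The genes with the lowest values in ERRγ-null relative to wild-type cortex were, after Xlr4a, 11 genes that did not pass the test. Cdkn1b, which encodes the cell-cycle inhibitor p27, had a log2 signal of 7.61 ± 0.07 in wild-type and 6.92 ± 0.39 in ERRγ-null cortex (SD, n = 2 each). The difference was -0.68 (SE 0.18, limma adjusted p = 0.414). Ppp1cb, a catalytic subunit gene of protein phosphatase 1, differed by -0.66, and its other probe by -0.65. Zdhhc17, a palmitoyltransferase gene, differed by -0.68, as did Dlx1as, the antisense transcript at the interneuron gene Dlx1. Rab11fip2, an adaptor gene for recycling endosomes, differed by -0.65, and Pcdhga10, a clustered protocadherin gene above background on 1 of the 4 null arrays, also by -0.65. Smim15 differed by -0.75 and Zc3h6 by -0.72. For 3 genes a second probe gave a smaller difference. These were Wdr13 with -0.69 and -0.28, Relch with -0.68 and -0.22, and Pcmtd1 with -0.63 and -0.30. Adjusted p for these 11 genes ran from 0.377 to 0.483. With the replicate number as a block 2 of the 11 passed, and with median scaling 0 did. Some also passed without 1 of the wild-type samples. None of the 11 passed in more than 2 refitted alternatives.

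**Figure D2:**
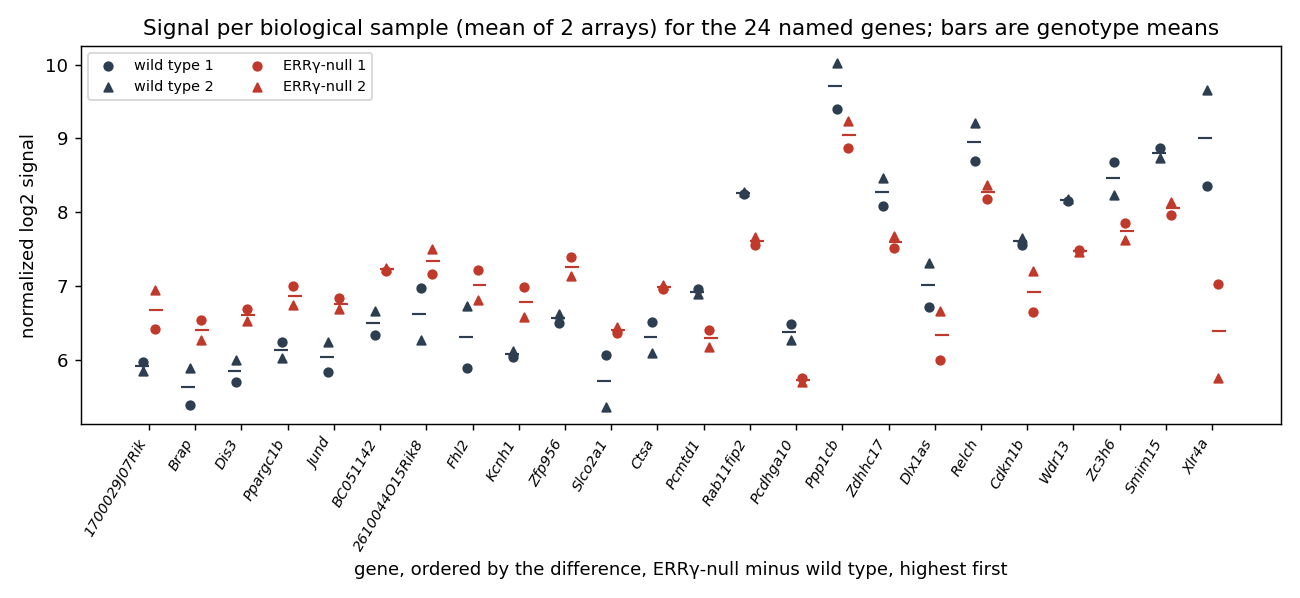
Normalized log2 signal of the 24 named genes in each biological sample (mean of 2 arrays), with wild type in dark blue and ERRγ-null in red, circles for sample 1, triangles for sample 2 and bars for genotype means. The genotypes do not overlap for any of these genes, which were selected for that property, and only Xlr4a (9.01 against 6.39) passed the test.

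Genes for oxidative phosphorylation, a process ERRγ is known to regulate, did not pass the test as a group. The 65 genes measured for complexes I to IV, cytochrome c and ATP synthase had a median log2 difference of 0.04, with 43 higher and 22 lower in ERRγ-null cortex (camera p = 0.238, and p = 0.396 with an estimated correlation). No member passed over all genes by limma, and 5 had an unadjusted p under 0.05, 4 of them higher. Complexes II to IV with cytochrome c had a median of 0.10, and 17 of 20 genes were higher (camera p = 0.0316, adjusted p = 0.521 over 37 lists, p = 0.144 with an estimated correlation). Their mean log2 signal was 10.71 and 10.69 in the wild-type samples and 10.81 and 10.78 in the null samples. The probe of the cytochrome oxidase subunit gene Cox7b was not above background on any wild-type array (mean 5.69 in wild type, 6.30 in null). Its measured mean was at least 1.25-fold higher in the null samples, a lower limit that does not include sampling error. Cox4i1 and Cox5b, of the same complex, lay at 13.02 and 13.22 in wild type, and Cox7a1 at 6.50. How well the only Cox7b probe reads its transcript was not tested. Cox7b passed when adjusted over the 20 genes of complexes II to IV with cytochrome c alone (limma adjusted p = 0.0307). It did not pass over the 65 genes (limma adjusted p = 0.0999) or over all genes. Sdhd of complex II differed by 0.41, and Ndufb10 and Ndufb4 of complex I by 0.39 and 0.51, where Ndufb4 was above background on 1 of 4 wild-type arrays. The lower gene among the 5 was Cox5a, a cytochrome oxidase subunit gene above background on all arrays, with -0.36. Its p had rank 3 in its list, so it is given outside the naming rule. Complex I had a median of 0.01 over 31 genes and ATP synthase 0.05 over 14. Without ERRγ-null sample 1 the median of the 65 genes was -0.000765, and without ERRγ-null sample 2 it was 0.07.

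Other metabolic groups also did not pass the threshold by camera after adjustment. Medians were 0.01 for 16 genes of pyruvate dehydrogenase and the TCA cycle, 0.08 for 15 genes of fatty acid oxidation, 0.05 for 14 genes of glycolysis and lactate handling and 0.07 for 16 genes of cholesterol synthesis. Single members differed by 0.49 for the glycolytic enzyme gene Pfkp, 0.46 for Etfb, 0.35 for the sterol transfer gene Stard4 and -0.38 for the carnitine palmitoyltransferase gene Cpt1b. The mitochondrial ribosome had a median of 0.03 over 48 genes, and mitochondrial fusion, fission and import 0.05 over 28 genes, where the import receptor gene Tomm70a differed by 0.43. The list of ERR family members, coactivators and biogenesis factors had a median of -0.05 over 14 genes, with 6 higher and 8 lower. Ppargc1b passed when adjusted over the list alone (limma adjusted p = 0.00512), whereas Gabpb1, a subunit gene of nuclear respiratory factor 2, differed by -0.41 and did not. The cytosolic ribosome, 35 genes, had a median of -0.01 and a mean of 0.01.

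Of 37 gene lists, 0 passed the threshold by camera after adjustment, and 3 had an unadjusted p under 0.05. With an estimated correlation 0 lists had an unadjusted p under 0.05, and by fry 2 did, with 0 past the threshold after adjustment. The p with an estimated correlation rests on 2 residual degrees of freedom, so its rise does not measure correlation between genes alone. For complexes II to IV that p rose although the estimated correlation was -0.017. The smallest adjusted camera p was 0.521. Besides complexes II to IV, the lists concerned were striatal markers and radial glia with intermediate progenitor markers. Striatal markers had a median of 0.15, with 9 of 10 genes higher (camera p = 0.0170, and p = 0.181 with an estimated correlation). The dopamine receptor gene Drd1 differed by 0.48, and the mean log2 signal of the list was 8.39 in each wild-type sample and 8.65 and 8.44 in the null samples. Radial glia and intermediate progenitor markers had a median of -0.09, with 10 of 11 genes lower (camera p = 0.0438, and p = 0.169 with an estimated correlation). In that list the intermediate filament gene Vim differed by -0.35 and Insm1 by -0.32. Under median scaling, relative to the shift of all genes, the radial glia median was -0.17 and the striatal median 0.14.

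**Figure D3:**
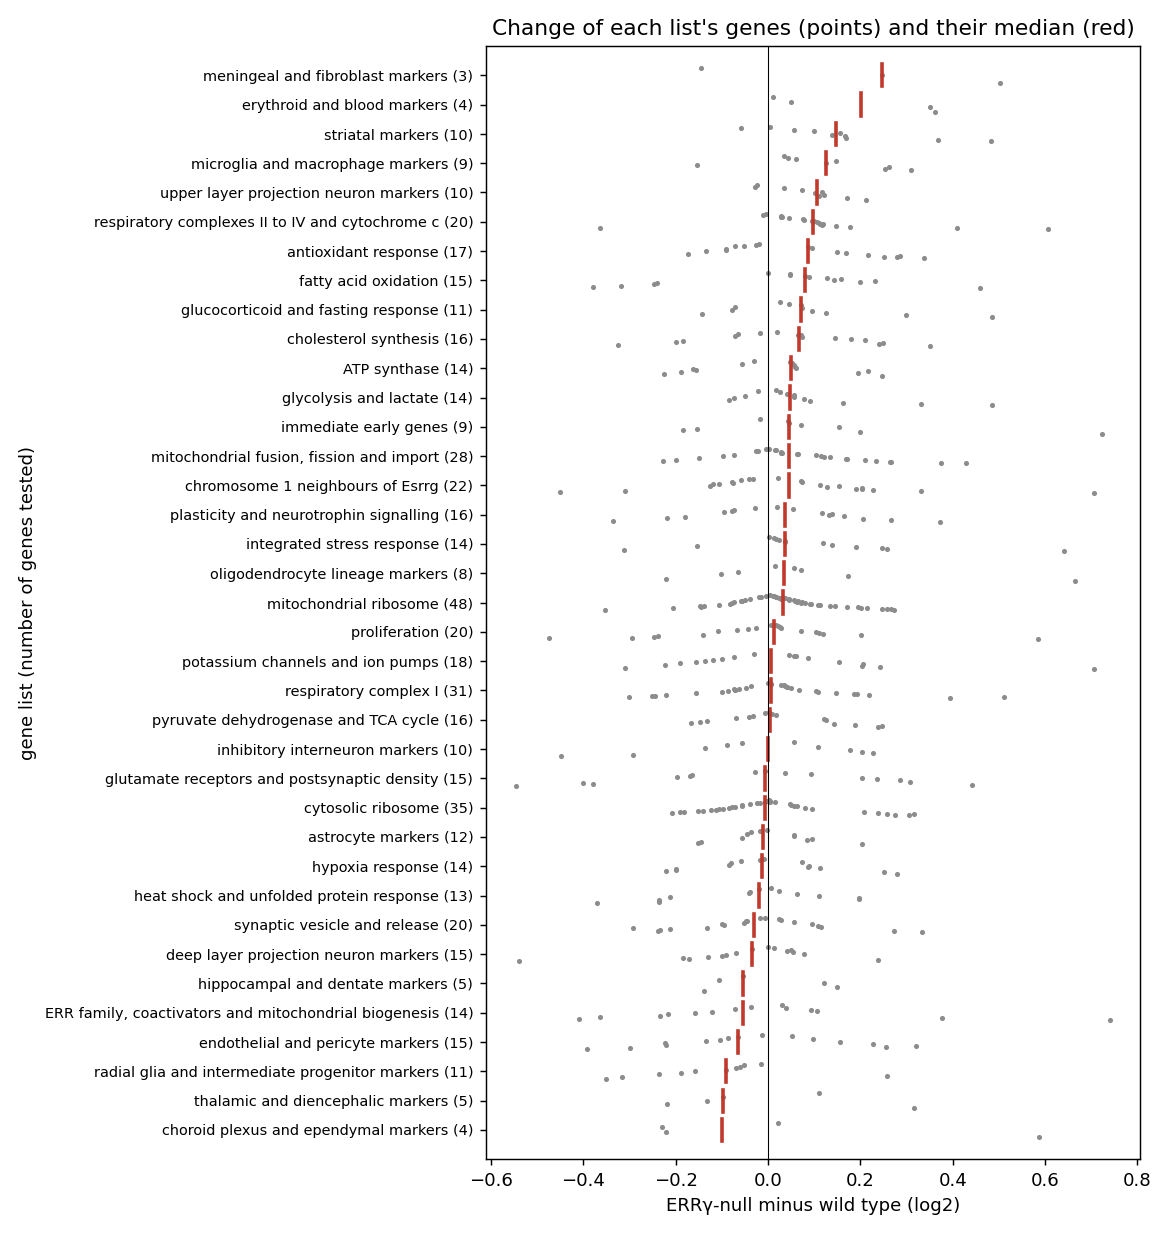
Log2 difference, ERRγ-null minus wild type, of each tested member (grey points) and the median (red bar) for the 37 gene lists, with the number of genes tested in parentheses. List medians run from -0.10 to 0.25, and members of most lists lie on both sides of 0.

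Neuronal gene groups had medians close to 0. These were -0.03 for synaptic vesicle and release genes (20 genes), -0.01 for glutamate receptors and the postsynaptic density (15), 0.04 for plasticity and neurotrophin signalling (16) and 0.01 for potassium channels and ion pumps (18). The kainate receptor gene Grik2, above background on 3 wild-type and 2 null arrays, differed by -0.55 and the adhesion gene Nlgn1 by 0.44. Immediate early genes had a median of 0.05 over 9 genes, where Jund passed when adjusted over the list alone (limma adjusted p = 0.00571), as did Kcnh1 among the potassium channels (limma adjusted p = 0.0135). Upper layer projection neuron markers had a median of 0.11 with 8 of 10 genes higher, and deep layer markers -0.04 with 8 of 15 lower. The limma camera adjusted p was 0.653 for the former list and 0.747 for the latter. Etv1, a layer 5 transcription factor gene, differed by -0.54 and passed when adjusted over the list alone (limma adjusted p = 0.0456). Inhibitory interneuron markers had a median of 0.00, with 5 of 10 genes lower, among them Calb2 with -0.45. Proliferation genes had a median of 0.01 and a mean of -0.02 over 20 genes, with Pcna at 0.58 and Hmgb2 at -0.47. The signs of the glutamate receptor, interneuron and proliferation medians, all within 0.02 of 0, were not the same under every normalization.

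Markers of other cell types and neighbouring regions gave no list past the threshold. Oligodendrocyte lineage markers had a median of 0.04 over 8 genes, and Gpr17, a receptor gene of oligodendrocyte precursors, differed by 0.67 and passed when adjusted over the list alone (limma adjusted p = 0.00469). Astrocyte markers had a median of -0.01 and a mean of 0.00 over 12 genes, microglia and macrophage markers 0.13 over 9 genes and endothelial and pericyte markers -0.06 over 15 genes. Hippocampal and thalamic markers, 5 genes each, had medians of -0.05 and -0.10. The 4 erythroid markers had a median of 0.20, and the 4 choroid plexus and ependymal markers a median of -0.10 but a mean of 0.04, with Sostdc1 at 0.59 (limma adjusted p = 0.0248 adjusted over the list alone). The 3 meningeal and fibroblast markers tested separated the null samples from each other. Their mean log2 signal was 8.40 and 8.38 in the wild-type samples, 8.05 in ERRγ-null sample 1 and 9.14 in ERRγ-null sample 2. Dcn, a proteoglycan gene of connective tissue above background on 2 of 4 arrays of each genotype, lay at 5.40 in ERRγ-null sample 1 and at 7.12 in ERRγ-null sample 2, and Igf2 at 10.34 and 11.37. Without ERRγ-null sample 1 this list had a median of 0.76 and passed by camera at the preset correlation. It did not pass with an estimated correlation, where few degrees of freedom were left. With all samples the list did not pass at the preset correlation, at a median of 0.25 (limma camera adjusted p = 0.816).

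Stress-related groups did not pass either. Medians were 0.04 for the integrated stress response (12 of 14 genes higher, limma camera adjusted p = 0.630), 0.09 for the antioxidant response (17 genes), 0.07 for glucocorticoid and fasting response (11), -0.01 for hypoxia (14, mean 0.00) and -0.02 for heat shock and the unfolded protein response (13). Slc3a2, an amino acid transporter subunit gene above background on 1 of 4 wild-type arrays, differed by 0.64 and passed when adjusted over the list alone (limma adjusted p = 0.0452). The 22 genes measured on a list of chromosome 1 neighbours of Esrrg had a median of 0.05, with 12 higher and 10 lower (limma camera adjusted p = 0.816). Kcnh1 passed when adjusted over this list alone (limma adjusted p = 0.0165), and Dusp10, a phosphatase gene above background on 2 of 4 null arrays, differed by -0.45. None of the genes that passed over a list alone passed over all 8098 genes.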

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

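The run without the dimmest array and the fits with a brightness trend alone or robust estimation alone were chosen after seeing the data, and the other alternatives before. The count of 1 gene past the threshold was also 1 without background correction, with cyclic loess, with the authors' normalized table, with the sample as a random block, with all arrays as if independent, at a threshold of 0.1, with a minimum log2 difference of 0.5, without the dimmest array and with a brightness trend in the variance prior alone. It was 20 with median scaling (19 higher, 1 lower). It was 0 by limma with no filter (1066 genes at an unadjusted p under 0.05), with the first arrays only (535), with the b arrays only (515), with robust variance estimation alone (585), with that and a brightness trend together (578) and with the mean of all probes (559). It was also 0 when a detection p under 0.01 was required on all arrays (430), a setting in which Xlr4a was not tested. The count ranged from 0 to 22 when 1 sample was left out, where the lone sample is assumed to vary like the other genotype. Prior degrees of freedom were infinite in the fits that gave 22, 17 and 12 genes, and 8.24 in those without an ERRγ-null sample. With a sample left out, the variances came only from the genotype that kept both samples. The prior was therefore 8.24 wherever that was the wild-type pair, and infinite wherever it was the null pair. What made it infinite was not tested.

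With the replicate number as a block (replicate block) the count was 12 (9 higher, 3 lower). Whether equal numbers mean anything shared between the genotypes is not given in the sources used here. The correlation across genes of their differences between samples 1 and 2 was 0.00815, which gives no sign of a pairing. It cannot exclude a weak one. Between the first and the b arrays, these differences correlated by only 0.124 in wild type and 0.251 in ERRγ-null. The block changed no call of a gene list. Xlr4a was lower in ERRγ-null cortex in all 19 refitted alternatives in which it was tested, by -3.27 to -1.73. It passed in 11 of them, with a limma adjusted p as high as 0.734 in the others. These passes are not independent, since they refit the same arrays. Among them are the fit with all arrays as if independent and the fits with infinite prior degrees of freedom. In the latter the spread of Xlr4a itself has no weight. The alternatives that changed only the threshold or set a minimum difference are not among the 19, and Xlr4a passed in each. The Esrrg difference, below background throughout, was -0.0644 with median scaling and ranged from -0.00436 to 0.0461 with 1 sample left out. The median of the 65 oxidative phosphorylation genes ranged from -0.000765 to 0.0690 with 1 sample left out and did not pass in any alternative. The number of gene lists past the threshold by camera was 0 in every alternative except without ERRγ-null sample 1, where it was 1 at the preset correlation, so that leaving out a sample gave 0 to 1. The cause of these differences was not tested. Of all values followed through the alternatives, 1194 were kept. A kept difference or median had the same sign and pass status, whatever its size, and a kept count stayed within a set factor. Another 128 moved, 37 newly passed and 8 no longer passed a threshold. Values that had not passed, such as Esrra in 3 of 20 alternatives, also changed sign, whereas Xlr4a did not. Genes at a low unadjusted p were more often dim than bright. Of the 585 genes at an unadjusted p under 0.05, 244 were in the dimmest of 5 equal groups by brightness and 29 in the brightest.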

Other observations

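The tests on sex, on related Xlr probes, on the origin of the wild-type arrays, on the variance of dim genes and on the neighbours of Esrrg were chosen only after the results were seen, as were the genes named in the next 2 paragraphs. Counting probes that were above background on all 4 arrays of 1 genotype and on none of the other gave 16 probes, 15 of them detected in ERRγ-null cortex only. The null arrays also detected more probes in general, 11376 to 12013 against 11022 to 11607, and their lowest log2 signal above background was 5.79 to 5.95 against 5.89 to 6.06. Among the 15 were probes of Icam1, which encodes an adhesion molecule of endothelium, the chemokine receptor gene Cxcr5, the extracellular matrix gene Olfml3 and the mitochondrial gene Cox7b. As lower limits that leave out sampling error, they were at least 1.22-fold, 1.06-fold, 1.16-fold and 1.25-fold higher in null cortex (limma adjusted p = 0.509, 0.509, 0.480 and 0.414). The 1 probe detected in wild-type cortex only was that of Slc39a12, a zinc transporter gene, at least 1.22-fold lower in null cortex (limma adjusted p = 0.480). The 16 probes lay close to background, and none of their genes passed the limma test.

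Of the other Xlr probes on the array, 7 in number, only that of Xlr5c was above background, on all 8 arrays, with a log2 difference of -0.30. The Y-linked genes Eif2s3y and Kdm5d were above background on all 8 arrays, with differences of -0.31 and 0.18. Among 782 probes without a gene symbol, 0 passed by limma, 59 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0555. Of the tested genes nearest Esrrg on chromosome 1, 50 before and 16 after it, 7.58% had an unadjusted p under 0.05, the same as the median of windows of that size.

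The difference of Xlr4a between the genotypes lay far below that of all other genes tested, and its signal also differed within each genotype, at 8.35 and 9.66 in wild type. A difference in sex is argued against as the source of the change of -2.61, since Eif2s3y differed by only -0.31 and was well above background in every array. Normalization and the dim array are argued against too, since the smallest fall over the normalizations and without that array was -1.73. Signal from other Xlr genes on the same probe stays open, because only 1 of the 7 other probes (-0.30) could be read. An effect of the receptor's loss, or a difference between the strains or litters the samples came from, may also account for the fall, and neither was tested. Variation between samples apart from genotype stays open as well. The null samples too lay far apart, at 7.02 and 5.76, and robust variance estimation did not give the call (limma adjusted p = 0.581).

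The arrays of wild-type sample 1 were about as far from each other (SD 0.345) as arrays of different samples were. Low brightness of its first array is a candidate explanation, since that SD was 1.16 times the median of the other technical pairs in the brightest of 5 groups of genes and 1.35 times in the dimmest. An array made from another sample also stays open, since the covariance across genes that the arrays of this sample share, measured against arrays of 2 different samples, was 0.00245, against 0.00992, 0.0186 and 0.00842 for the other samples. It was above 0 in 13 of 16 combinations of arrays, and a sample that differs little from the others could give the same value. No biological explanation was tested.

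More genes than a uniform distribution gives had an unadjusted p under 0.05, 585 against 404.9. A larger variance of dim genes is argued against as the whole cause, since 579 genes were found with a variance prior that follows brightness. The 4 samples make only 3 splits into 2 and 2, too few for a share under 0.05. The real split was the 1 with the most genes, where the highest other gave 355, and the 1 with the most probes detected in a single group, 16 against 7. Whether the genotype, or another difference between these few samples, may account for the excess stays open.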
